A study of Mus musculus with 4 samples.

How the data were processed

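Gene expression was measured in ureters dissected from mouse embryos of the NMRI strain at embryonic day 15.5. Embryos that carried Pax2-cre and 2 floxed ΔN alleles of Trp63, called cKO here, were compared with control embryos with at least 1 floxed allele, whose genotype lists no cre, per the labels. The 4 samples of the series are 4 arrays with 2 channels, each holding 1 cKO RNA and 1 control RNA of the same sex. Replicates 1 and 2 are female and replicates 3 and 4 male. The cKO RNA carried AlexaFluor647 (red) in replicates 1 and 3 and AlexaFluor555 (green) in replicates 2 and 4, per the labels. Each labelling started from 200 ng of total RNA with 1 round of T7 amplification, per the labels' protocols.

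The deposited scanner files hold spot intensity values: the mean signal and the median local background of each spot in both channels, made with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The same files hold processed intensities, which the software had background-subtracted, detrended and dye-normalized, per the file headers. They also hold flags of other kinds (well above background, nonuniform, saturated), as deposited. Each array has 174979 spots, of which 157716 belong to 39429 gene probes with 4 spots each. All 4 arrays lie on 1 slide with 1 scan date, so neither forms a batch. The probe coordinates are of build mm9 (NCBI build 37), per the file headers. The value table deposited with the series holds log2 ratios. Set against the processed signals of each array, its values had a slope of 1 (replicate 1), -0.999 (replicate 2), 0.999 (replicate 3) and -1 (replicate 4) for red over green over 19384 to 20771 bright probes, so the table gives cKO over control with the dye orientation already turned. Each column has a median of 0, and 32.2% to 32.6% of its values are exactly 0. How the authors set those zeros is not given in the sources used here.

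For the main values, background was corrected with normexp (offset 50, all spots), log2 ratios were normalised by loess within each array with control spots at weight 0, and nonuniform spots were left out (17 to 33 per array). No spot was saturated. The spots of a probe were averaged. A probe was kept where a share of at least 0.5 of its spots was well above background on all 4 arrays in the control RNA or on all 4 in the cKO RNA. This kept 28611 probes. Each gene was represented by its kept probe with the highest mean intensity, whatever its ratio, which gave 21501 genes, 21500 of them with all 4 ratios. Of the 39429 probes, 30385 carry a symbol found in the reference gene table (assembly GRCm38.p6, used for names only), 1442 were named through an accession, and 7602 kept the name in the file.

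The log2 ratios of cKO over control were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), with 1 coefficient for cKO over control and 1 intercept for the probe-specific dye effect. Since each array holds 1 cKO and 1 control RNA, the array is the pair. The p-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with adjusted p under 0.05 were called changed. All adjusted p-values given for genes come from limma. Errors are SDs of the 4 log2 ratios. Of 32 gene lists, 31 were tested with camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry beside it. The remaining list, of sex chromosome genes, was used only to check labels. Lists with fewer than 5 tested genes would not have been tested. A cKO-by-sex coefficient tested whether the effect differed between sexes, and the intercept tested the dye effect. Where a gene was not well above background in 1 of the RNAs on every array, a lower bound of its fold was computed from channel values after loess and Aquantile normalisation, with the lowest signal of any probe above background in place of dimmer values.

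The genes named are Trp63, the 12 largest decreases and 12 largest increases among changed genes with the same sign on all 4 arrays (leaving out clone and unnamed features), up to 4 members of each list with the smallest p, and members that changed against their list. Other list members serve as examples with their values. A further 6 marker lists, a fit to replicates 2 and 3 alone without the dye term, a sex test without it and a permutation of genes between the basal and general epithelial lists (100000 draws) were chosen after seeing the data. Exon positions of the probes, and whether they lie in the floxed part of Trp63, were not analysed here. Results of some genes are not reported here.

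The fit was tested on simulated ratios for 21501 genes and 4 arrays, with 200 genes changed in each of 10 rounds. It recovered 46.7% of genes changed by 1.5-fold, 91.9% of those changed by 2-fold and 99.6% of those changed by 4-fold, with no wrong sign, and 4.28% of its calls were false. With no gene changed, at most 2 genes were called in a round, and at most 3 for a sex difference. The simulation drew independent genes with normal errors, so it does not cover errors shared between genes.

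The gene lists, the rule for named genes, the comparisons and 20 alternatives were fixed before the data were examined. The alternatives covered background, normalisation, filter, dye term, sex term, array weights, variance moderation, the choice of probe, the channels as separate RNAs, the deposited value table, a 1.5-fold minimum, and leaving out each array in turn. The number of arrays limits the precision. The labels do not say whether an RNA came from 1 embryo or a pool, so the spread between arrays holds an unknown share of technical variation. The dye term takes up the difference between the dye orientations. The p-values therefore rest on the spread between arrays of the same orientation, each such pair being 1 female and 1 male array. That spread has 2 residual degrees of freedom, and limma moderated it with 4.075 prior degrees of freedom. The SDs of all 4 log2 ratios also hold the difference between orientations, so they are not the spread behind the p-values.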

Results

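Total RNA of whole ureters from E15.5 mouse embryos (NMRI strain) was compared between ΔNp63-cKO and control embryos on 4 arrays. In the cKO genotype, Pax2-cre recombines a floxed Trp63 allele that targets the ΔN form of p63, a transcription factor of basal cells in stratified epithelia. The comparison asks which transcripts of the embryonic ureter differ between these genotypes. Pax2-cre is listed for every cKO RNA and for no control RNA. For every gene, an effect of the cre transgene thus cannot be told apart from loss of ΔNp63. Each array set 1 cKO RNA against 1 control RNA of the same sex, with 2 female and 2 male arrays and each dye used for cKO on 2 arrays. Median signals per array were 382 to 416 in the green and 519 to 617 in the red channel. Between 74.9% and 77.0% of gene probe spots were well above background in the green channel, and between 71.8% and 73.2% in the red channel. The arrays' ratios correlated across all genes with a Pearson r from -0.06 (replicates 2 and 4) to 0.62 (replicates 2 and 3). The Spearman rho of replicates 2 and 4 was -0.32. Genes are not independent replicates. Dyes and directions are those the labels state.

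Trp63, the targeted gene, was lower in cKO RNA on every array. Its representative probe (A_51_P216550, chromosome 16, 25892012 to 25892071, mm9) gave log2 ratios of -1.39, -1.18, -1.30 and -1.62 in replicates 1 to 4, a mean of -1.37 ± 0.18 (SD, n = 4), or 2.59-fold lower, with adjusted p = 0.00323. Another Trp63 probe (A_55_P1952056, chromosome 16, 25821344 to 25821403) gave -1.26 ± 0.36, and a further one (A_52_P338796, chromosome 16, 25867718 to 25867777) gave -0.81 ± 0.34 and did not pass the test when every probe was tested by itself (adjusted p = 0.0545). The remaining Trp63 probe (A_55_P2161055, chromosome 16, 25871159 to 25871218), whose sequence holds a run of CAG repeats, gave -0.02 ± 0.16. Whether any of these probes lies inside the floxed part is not given in the sources used here, so a probe outside it would not check the deletion.

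Of 21501 genes tested, 153 were lower and 113 higher in cKO ureters. Without replicate 1, 171 genes were higher; 509 were lower and 430 higher without replicate 2, and 855 lower and 753 higher without replicate 4. The largest decrease was that of Serpinb5, which encodes the serpin maspin, at -2.35 ± 0.32 (SD, n = 4) or 5.09-fold (adjusted p = 0.00175). It was followed by Anxa8, an annexin, at -2.31 ± 0.43, Dapl1 at -2.12 ± 0.25, Perp, a desmosome-associated membrane protein, at -2.12 ± 0.36, and Pkp1, a desmosomal plaque protein, at -2.11 ± 0.29. Slc14a1, a urea transporter, was lower at -1.92 ± 0.30, Trim29 at -1.88 ± 0.12, and Krt5, the keratin of basal cells (chromosome 15, 101537514 to 101537573), at -1.87 ± 0.42. Zfp750, a transcription factor of epidermal differentiation, Lypd3, the ligand gene Wnt10a and the uroplakin-related Upk3bl completed the 12 largest decreases at -1.86 ± 0.20, -1.86 ± 0.19, -1.80 ± 0.09 and -1.74 ± 0.18. These 12 genes had adjusted p-values from 0.000855 to 0.00347, and each was lower on all 4 arrays.

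**Figure D1:**
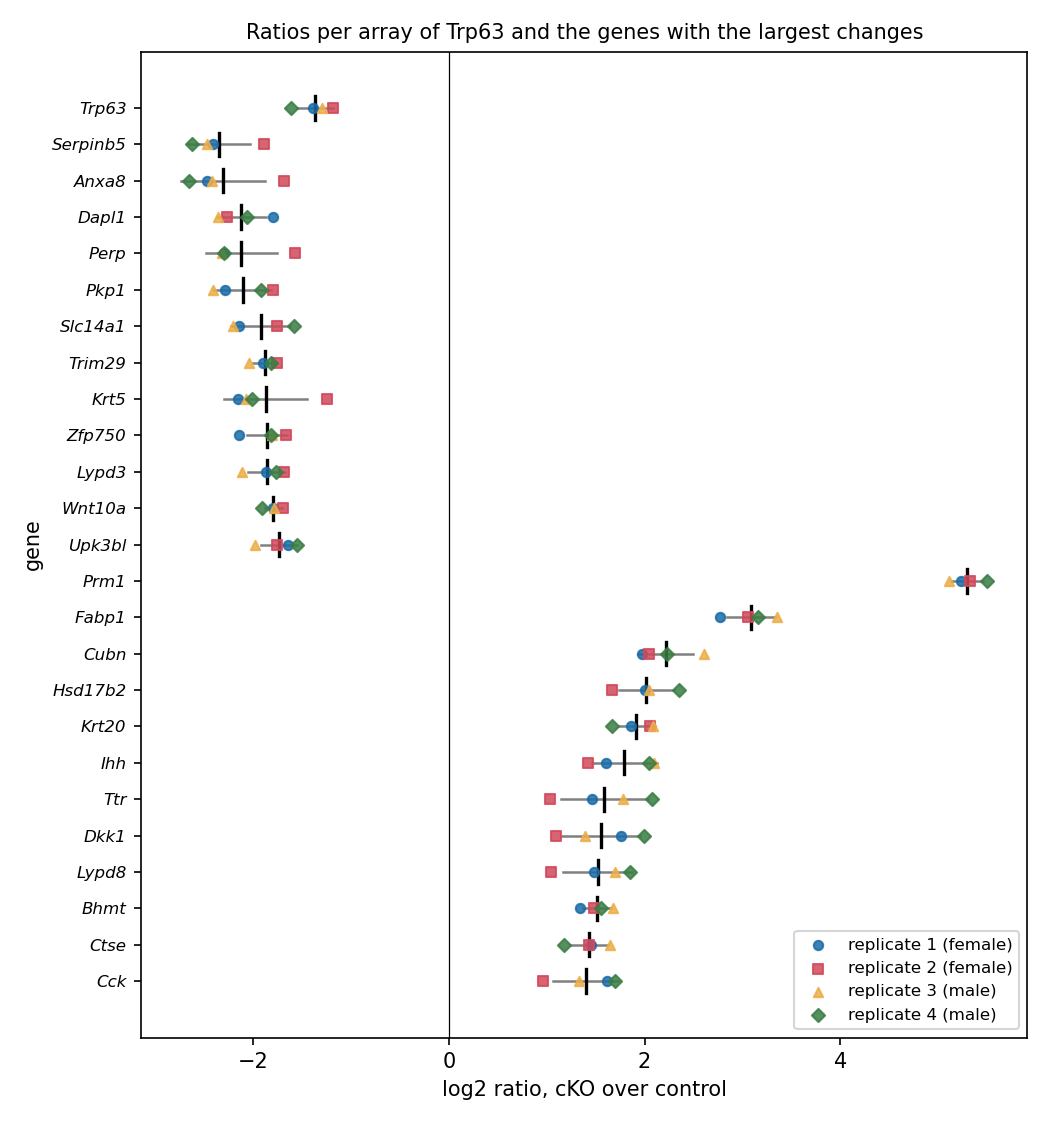
Log2 ratio of cKO over control on each of the 4 arrays (coloured symbols) for Trp63 and the 12 largest decreases and 12 largest increases, with the mean (black tick) and 1 SD on either side (grey line). Every symbol of a decreased gene lies below 0 and every symbol of an increased gene above 0, with Prm1 at 5.29 as the largest change.

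The largest increase was that of Prm1, the gene of protamine 1, a DNA-packing protein of sperm (chromosome 16, 10796450 to 10796509), at 5.29 ± 0.16 or 39.2-fold (adjusted p = 1.09e-05). Its level was 12.6 to 12.9 in the cKO RNAs and 7.37 to 7.47 in the control RNAs (normalised log2 intensity). Fabp1, a fatty acid binding protein of liver and intestine, rose by 3.09 ± 0.24 or 8.49-fold, and Cubn, an endocytic receptor of the kidney proximal tubule, by 2.22 ± 0.28. Hsd17b2, a steroid dehydrogenase, rose by 2.02 ± 0.28, Krt20, a keratin of superficial urothelial cells, by 1.92 ± 0.19, and the ligand gene Ihh by 1.79 ± 0.33. Ttr, a carrier of thyroid hormone, rose by 1.59 ± 0.44, the Wnt inhibitor gene Dkk1 by 1.56 ± 0.40, Lypd8 by 1.52 ± 0.35, Bhmt, a methyltransferase, by 1.51 ± 0.14, the protease gene Ctse by 1.43 ± 0.19 and the peptide hormone gene Cck by 1.40 ± 0.33. Each of these 12 genes was higher on all 4 arrays, with adjusted p-values from 1.09e-05 to 0.0145.

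In all, 266 genes changed (limma, adjusted p under 0.05), 263 of them with the same sign on all 4 arrays, 220 by at least 1.5-fold, and 94 by at least 2-fold (54 lower, 40 higher). The median log2 ratio was -0.80 over the lower genes, 0.83 over the higher genes and -0.000237 over all genes. Of the changed genes, 62 had further kept probes, and 67 of these 69 probes had the same sign. The sign alone does not give the size. The further probe of Ripk4 matched (-0.82 for both). That of Pls1 was at 4.18e-07 against 0.62, and that of Col4a6 at -0.19 against -0.80. Some changed genes were not well above background in 1 of the RNAs on any array. Among these, named here after their values were seen, Ces2f was at least 1.51-fold lower in cKO and Cyp4a32 at least 1.66-fold higher. The size of the count depended on the arrays used: without replicate 2 the genes changed numbered 939, and without replicate 4 they numbered 1608. In these 2 fits the dye term fitted 1 array exactly, so the residual spread came from replicates 1 and 3 alone. Limma's prior degrees of freedom were 8.449 in both. Without replicate 1 or 3 the spread came from replicates 2 and 4 alone. The prior degrees of freedom were then infinite, so every gene was given the same variance. The counts, and the misses of single genes without replicate 1 or 3 given below, thus reflect the variance model and the pair that gave the spread, as well as the array left out. Without a filter on dim probes 86 genes changed, all of them among the 266. Taken as 8 separate RNAs without the pairing on each array, the channels gave 387 changed genes, 239 of them shared with the 266.

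Of 18 basal cell markers tested, 8 fell and none rose (9 and 2 when adjusted over the list alone): Dapl1, Cdh3 (-1.66 ± 0.42, P-cadherin), Krt5, Krt6a (-0.85 ± 0.17), Itgb4, Krt15 (-1.19 ± 0.31), Krt14 (-0.98 ± 0.29) and Krt17 (-0.67 ± 0.24). The basal list shifted lower (camera, adjusted p = 2.16e-09), with adjusted p = 0.318 with an estimated correlation and 0.00894 by fry. Its mean log2 ratio was -0.57 and its median -0.20, and 10 of the 18 markers did not change, so the shift rests largely on the 8 that fell. Of 35 published p63 targets, 15 fell and none rose (18 and 1 when adjusted over the list alone). Among them were Zfp750, Sfn (-1.30 ± 0.20), Perp, Jag2 (-1.22 ± 0.15), Tfap2c (-1.11 ± 0.21), Nectin1 (-0.96 ± 0.03), Gjb6 (-1.05 ± 0.24), Tgm1 (-0.95 ± 0.22) and Gjb2 (-0.86 ± 0.19). The p63 target list had adjusted p = 6.40e-24 (median -0.32), with adjusted p = 0.318 with an estimated correlation and 0.0532 by fry. Of the 18 basal markers 7 are also on another list, and of the 35 targets 15. Without a filter on dim probes, 3 basal markers and 8 p63 targets fell. Without replicate 3, Krt17 missed the threshold at -0.57 (adjusted p = 0.0624).

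Of 14 genes of desmosomes and cornified envelope linkers, 4 fell and none rose (6 and 1 when adjusted over the list alone): Pkp1, Sfn, Perp and Ppl (-0.59 ± 0.12). Of 20 genes of hemidesmosomes and the epithelial basement membrane, 3 fell and none rose (5 and 0 when adjusted over the list alone): Fermt1 (-1.41 ± 0.27), Itgb4, the beta chain of the hemidesmosomal integrin (-1.45 ± 0.36), and the collagen chain gene Col4a6 (-0.80 ± 0.19). A further probe of Col4a6 gave -0.19. The desmosome list had adjusted p = 8.21e-07 and the hemidesmosome list 3.12e-05 (camera), and both had adjusted p = 0.588 with an estimated correlation. The median of the hemidesmosome list was 0.12 in replicate 2 and negative in the others. By fry, the adjusted p was 0.176 for desmosomes and 0.325 for hemidesmosomes. Another list also holds 2 of the desmosome and 5 of the hemidesmosome genes. The basal, p63 target, desmosome and hemidesmosome lists together held 77 genes, of which 25 fell and none rose. Without a filter on dim probes 0 hemidesmosome genes passed the test (limma; 5 lower at an unadjusted p under 0.05 with the filter), and without replicate 2 or without replicate 4 there were 5. Without replicate 4 the hemidesmosome list had adjusted p = 0.109.

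**Figure D2:**
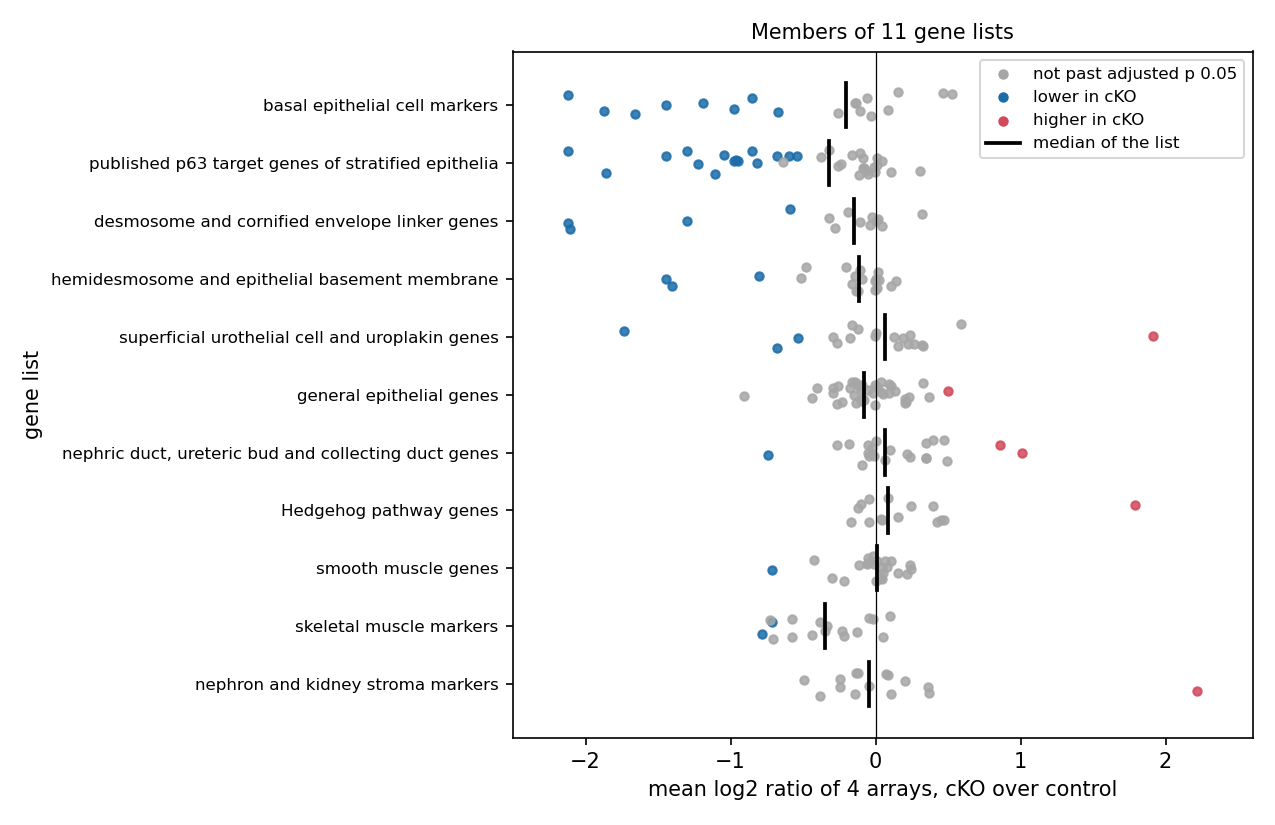
Mean log2 ratio of cKO over control (x axis, 4 arrays) of each member of 11 gene lists (y axis), coloured by whether the gene passed adjusted p 0.05 in limma, with the median of each list as a black line. Changed members of the basal and p63 target lists all lie below 0. The medians of the whole lists are -0.20 (basal), -0.32 (p63 targets) and -0.08 (general epithelial).

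Other epithelial genes moved in both directions. Of 20 genes of superficial cells and uroplakins, Upk3bl, Upk2 (-0.54 ± 0.11) and Grhl3 (-0.68 ± 0.22) fell and Krt20 rose (3 lower and 5 higher when adjusted over the list alone), and the list did not pass the test (camera adjusted p = 0.700). Without a filter on dim probes, 1 superficial gene fell, and 1 with the deposited value table. Upk2 missed the threshold without replicate 1 (-0.52, adjusted p = 0.107) and without replicate 3 (-0.55, adjusted p = 0.0889). Of 39 general epithelial genes, Krt18 rose (0.50 ± 0.14) and none fell (2 and 2 when adjusted over the list alone). Krt8 was at 0.37 ± 0.19 and Cdh1, E-cadherin, at -0.40 ± 0.26, neither past the threshold, and the list did not pass the test (adjusted p = 0.198). Krt18 missed the threshold without replicate 1 (0.49, adjusted p = 0.177) and without replicate 3 (0.51, adjusted p = 0.158). Of 23 genes of the nephric duct, ureteric bud and collecting duct, Tfcp2l1 (1.01 ± 0.15) and Wnt9b (0.86 ± 0.18) rose and Elf5 fell (-0.74 ± 0.24), with 7 higher and 1 lower when adjusted over the list alone. That list shifted higher (adjusted p = 0.00620), with adjusted p = 0.588 with an estimated correlation, 0.325 by fry and 0.367 without replicate 4. Of 17 genes of squamous differentiation, Dmkn (0.65 ± 0.19) and Sprr1a (0.69 ± 0.20) rose and Tgm1 fell (3 and 3 when adjusted over the list alone), and the list did not pass the test (adjusted p = 0.675).

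Of 15 Hedgehog pathway genes, Ihh rose and no other passed the test over all genes (6 higher when adjusted over the list alone). The pathway's target genes Ptch1 (0.42 ± 0.10), Hhip (0.47 ± 0.27) and Gli1 (0.24 ± 0.07) had positive ratios on all 4 arrays without passing the threshold. The Hedgehog list shifted higher (camera adjusted p = 0.00223), with adjusted p = 0.517 with an estimated correlation and 0.176 by fry. Of 29 Wnt pathway genes, Dkk1, Wif1 (1.04 ± 0.21) and Wnt9b rose and Wnt10a and Wnt4 (-0.60 ± 0.07) fell (4 and 2 when adjusted over the list alone), and the list did not pass the test (adjusted p = 0.675). Without a filter on dim probes 0 Wnt genes rose (limma; 5 higher at an unadjusted p under 0.05 with the filter), without replicate 2 there were 5, and without replicate 1 Wnt4 missed the threshold at -0.57 (adjusted p = 0.0528). Of 18 Notch pathway genes, the ligand gene Jag2 fell (4 lower when adjusted over the list alone), and Nrarp (-0.51 ± 0.17) and Notch1 (-0.36 ± 0.14) did not pass. The Notch list shifted lower (adjusted p = 0.00223), with adjusted p = 0.588 with an estimated correlation, 0.263 by fry and 0.199 without replicate 2. Of 21 BMP and TGF-beta genes, Bmp2 rose (1.19 ± 0.15; 1 higher when adjusted over the list alone), and of 16 retinoic acid genes, Aldh1a1 fell (-1.29 ± 0.20; 2 lower when adjusted over the list alone). Neither list passed the test (adjusted p = 0.552 and 0.198). Of 20 FGF and receptor tyrosine kinase genes 0 changed (limma; 3 lower and 4 higher at an unadjusted p under 0.05; 1 higher when adjusted over the list alone), and the list had adjusted p = 0.4999.

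Of 25 genes of the ureteric mesenchyme, lamina propria and adventitia 0 passed the threshold (limma; 1 higher at an unadjusted p under 0.05; camera adjusted p = 0.720 for the list). Of 23 smooth muscle genes, Ckm fell (-0.71 ± 0.26; 1 lower when adjusted over the list alone), which is also on the list of skeletal muscle markers, and the list did not pass the test (adjusted p = 0.675). Its median of 0.01 differed in sign from its mean of -0.03 and from the direction of the test, lower, and without replicate 3 it passed (adjusted p = 0.0200). Cell cycle (adjusted p = 0.620), p53 response (0.620), interferon and inflammation (0.121), mitochondrial respiratory chain (0.323), erythroid (0.324) and fat cell lists (0.198) had 0 changed genes (limma), also when adjusted over the list alone. At an unadjusted p under 0.05 there were 0 cell cycle, 1 p53 response, 3 interferon, 0 mitochondrial, 2 erythroid and 1 fat cell gene. Without replicate 3 the erythroid list passed, lower, with adjusted p = 0.0265.

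Skeletal muscle markers shifted lower (camera adjusted p = 1.22e-09, median -0.35), negative on all 4 arrays, with Myl1 (-0.78 ± 0.12) and Ckm lower among 17 genes (7 lower when adjusted over the list alone). The adjusted p was 0.588 with an estimated correlation and 0.188 by fry. Immediate early and dissection stress genes shifted higher (camera adjusted p = 4.56e-05, median 0.13), with adjusted p = 0.517 with an estimated correlation and 0.176 by fry. The medians of this list were -0.02 and -0.13 in replicates 1 and 3, with the cKO RNA in red. They were 0.25 and 0.40 in replicates 2 and 4, with the cKO RNA in green. The sign thus followed the dye, and a dye effect on the list was not tested. Of its 22 genes 0 changed (limma, with 1 lower and 9 higher at an unadjusted p under 0.05, and 1 higher when adjusted over the list alone). Neuron and glia markers (adjusted p = 0.00705) and macrophage and leukocyte markers (adjusted p = 0.0244) shifted lower and endothelial markers (adjusted p = 0.0164) and hypoxia and glycolysis genes (adjusted p = 0.0125) higher. None of these last 4 lists held a changed gene (2 higher for hypoxia and 0 for the others when adjusted over the list alone), and each had adjusted p = 0.588 with an estimated correlation. By fry, the adjusted p was 0.431 for neuron and glia, 0.325 for macrophage, 0.344 for endothelial and 0.176 for hypoxia. At an unadjusted p under 0.05 (limma), 2 neuron and glia genes and 5 macrophage and leukocyte genes were lower, 1 macrophage and leukocyte gene and 3 hypoxia genes were higher and 0 endothelial genes passed. The neuron and glia list missed the threshold without replicate 2 (adjusted p = 0.470), the macrophage list without replicate 1 (0.231), 2 (0.230) or 3 (0.189), the endothelial list without replicate 3 (0.324) or 4 (0.281), and the hypoxia list without replicate 1 (0.231) or 4 (0.175). With a sex term the macrophage (adjusted p = 0.205), endothelial (0.107) and hypoxia (0.107) lists missed it, and the macrophage list also did with Agilent's processed signals (0.0612) and with median centring (0.0640). Of 15 nephron and kidney stroma markers, Cubn rose (3 higher when adjusted over the list alone). The list's medians were 0.00, -0.23, -0.01 and 0.32 in replicates 1 to 4, and its median of -0.05, mean of 0.11 and test direction (higher, adjusted p = 0.241) differed in sign. Without replicate 2 it passed, higher, with adjusted p = 0.000135, and without replicate 3 with adjusted p = 0.0241. Of 11 mesothelial markers, Msln rose (1.05 ± 0.11; 1 higher when adjusted over the list alone; adjusted p = 0.323 for the list). Of 15 adrenal, gonad and genital duct markers 0 changed (limma; 2 higher at an unadjusted p under 0.05; 1 higher when adjusted over the list alone; adjusted p = 0.966, with a median of -0.03 and a test direction of higher).

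Whether the response differed between female and male ureters was tested with a cKO-by-sex coefficient. It called 15 genes, among them Hsd3b4, a steroid dehydrogenase gene, with a male minus female difference of 1.89 ± 0.27 (SE) and adjusted p = 1.96e-08, and Hsd3b1 at -1.62 (adjusted p = 1.08e-05). The ratios of Hsd3b4 were -0.38 and -2.16 on the female arrays and -0.18 and 1.42 on the male arrays. The fit left 1 residual degree of freedom, and limma gave every gene an SE of 0.27. These p-values therefore do not measure a gene's own spread between arrays of the same sex. Without the dye term 0 genes passed (limma, 268 at an unadjusted p under 0.05), and without a filter on dim probes 0 (178). Both unadjusted counts are below the share of 0.05 of the genes tested that chance alone gives. The transcripts of sex chromosome genes followed the labelled sex, with intermediate levels on 2 arrays in both RNAs. On the array of replicate 1, labelled female, Ddx3y was at 8.68 in control and 8.46 in cKO RNA, against 6.27 and 6.45 in replicate 2 and 12.01 to 12.33 in the male replicates. On the array of replicate 4, labelled male, Xist (probe A_52_P300376) was at 9.45 and 9.68, against 6.53 and 6.79 in replicate 3 and 12.6 in the female replicates. These are 1 of the 2 arrays of each labelled sex, so the female against male comparison rests on labels that the transcripts of replicates 1 and 4 match only in part. With the arrays of replicates 1 and 4 left out and, since 2 arrays cannot also carry it, no dye term, a choice made after the data were examined, 683 genes were lower and 881 higher, 261 of the 266 genes still passed in the same direction, and 8 basal markers and 15 p63 targets were lower. The 266 were called with replicates 2 and 3 included, and these had the highest Pearson r of any pair over all genes. The overlap is therefore not an independent check. In that fit 7 of the 13 shifted lists missed the threshold: desmosome (adjusted p = 0.130), hemidesmosome (0.277), nephric duct (0.426), immediate early and dissection stress (0.338), hypoxia (0.426), endothelial (0.147) and macrophage (0.125). Dropping the dye term alone, with all 4 arrays, gave 460 changed genes and 13 shifted lists.

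**Figure D3:**
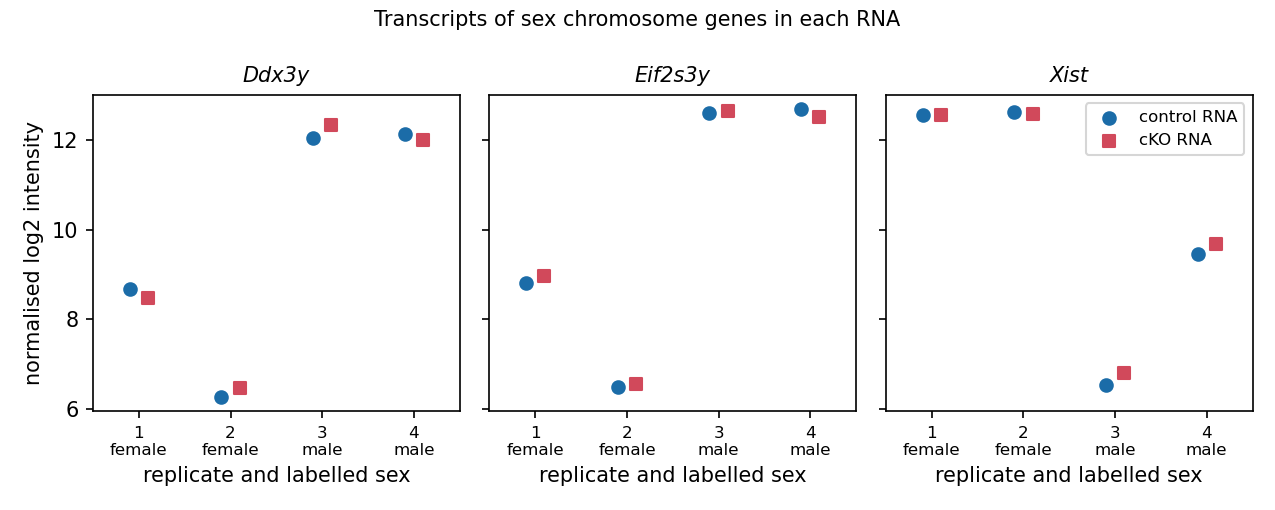
Normalised log2 intensity (y axis) of Ddx3y, Eif2s3y and Xist in the control RNA (circles) and cKO RNA (squares) of each replicate, with the labelled sex (x axis). In replicate 1 the Y-linked genes Ddx3y and Eif2s3y lie between the levels of replicate 2 and the male replicates, and in replicate 4 Xist lies between replicate 3 and the female replicates.

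The dye effect, common to all arrays of 1 probe, passed the threshold for 0 genes (limma, 429 at an unadjusted p under 0.05). The 429 are below the share of 0.05 of the genes tested that chance alone gives. The dye effect was tested gene by gene and not for the gene lists.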

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

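The tests of a Prm1 sequence in the transgene, of liver and intestine genes taken apart, and of the share of epithelium were chosen after the results were seen.

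With 8 patterns of signs over the 4 arrays, a share under 0.05 cannot be had for the 266 changed genes. The real pattern, 1 of the 8, gave 266 and the highest of the others 0. The pattern that follows the dyes was fitted without the dye term, since the term and the pattern coincide.

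Prm1 was higher in cKO RNA by 5.29 on the log2 scale on average over the 4 arrays, to levels of 12.6 to 12.9. The 22 spermatid and germ cell genes listed after the data were examined had a median log2 ratio of -0.012. Of these genes, 8 were above background in the cKO RNA on all arrays. Tnp1 was at 0.06 (mean level 7.31) and Prm2 at -0.01 (mean level 6.80). These values argue against RNA of germ cells as the source, although ratios taken at background carry little weight. A Prm1 sequence carried by the cre transgene may be the source, because some transgene constructs end in a Prm1 segment. The 4 ratios had an SD of 0.165 and the 9 neighbours of Prm1 on chromosome 16 a median of -0.014. Since cre is listed for every cKO RNA and for no control RNA, and the transgene's sequence is not given in the sources used here, this cannot be told apart from a response of the gene to the loss of ΔNp63.

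Fabp1 and Cubn rose, which RNA of a neighbouring organ could produce. The 14 nephron and kidney stroma genes other than Cubn had a median of -0.083, with medians of -0.02, -0.27, -0.04 and 0.27 in replicates 1 to 4, while Cubn was higher on all 4. This argues against more kidney tissue as the whole cause, although the list with Cubn passed, higher, without replicate 2 (adjusted p = 0.000135) or without replicate 3 (adjusted p = 0.0241). The 18 tested fetal liver genes had a median of -0.30, negative on each array, with Alb at -0.71 ± 0.54 (mean level 11.4) and Afp at -0.72 ± 0.53 (mean level 12.3), which argues against liver RNA, although Ttr rose. RNA of intestine stays open, since its 5 tested genes had a median of 0.19 (SD over genes 0.45). Lgals4 (1.14 ± 0.28, mean level 11.97) was higher. Vil1 was at 0.56 ± 0.28 (mean level 7.717) and Cdx1 at 0.19 ± 0.35 (mean level 7.356). Fabp2 was at 0.09 ± 0.09 (mean level 7.536) and Muc13 at 0.06 ± 0.12 (mean level 8.317). Cdx2, also on the intestine list, was above background on 0 arrays in either RNA (mean level 6.208) and was not tested. Its ratio, taken at background, cannot decide. A change within ureter cells stays open too, and was not tested.

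Of the basal markers 8 fell, and a lower share of epithelium in the cKO ureters could lower them. It would lower the other epithelial genes alike, and the 39 general epithelial genes had a median of -0.078 (SD over genes 0.25). The smallest decrease among the 8 was -0.67 (Krt17). The 8 were picked for passing the threshold, so their decreases are large by that choice and this gap cannot decide. The median of the basal list lay below that of the general epithelial list on each array, by -0.29 ± 0.10 (mean and SD of 4 arrays; two-sided permutation of genes between the lists, p = 0.00074), which argues against a smaller epithelium as the whole cause. Taken over the mean ratios of the genes, the medians differed by -0.12 and the same permutation missed the threshold (p = 0.0656), so for the list as a whole the argument depends on how the lists are summarised, and genes are not independent. A smaller epithelium as part of the cause, fewer cells with these transcripts and lower transcription within such cells stay open, since whole ureters were measured. Which cells carried these transcripts was not measured.

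Of 89 values tested for 1 array far from the other 3 (58 named genes and 31 list medians), 6 stood out, where chance gives about 1 in 20. The gap to the nearest array divided by the range was 0.964 for Perp (replicate 2 at -1.58, the others near -2.30), 0.836 for Krt5 (replicate 2 at -1.24) and 0.84 for Wnt4 (replicate 3 at -0.49). It was 0.873 for the median of the Hedgehog list (replicate 4 at 0.04), 0.856 for that of the Notch list (replicate 4 at 0.18, the others negative) and 0.836 for that of the hypoxia and glycolysis list (replicate 3 at 0.01).

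The cKO-by-sex test called 15 genes, with the same SE of 0.27 for every gene. Its p-values therefore do not measure a gene's own spread, and a difference between the sexes is not established for these genes. Among them, male minus female differences were 1.89 for Hsd3b4, 1.51 for S100g, 1.47 for Spp2, 1.25 for 2610507I01Rik and 1.19 for Nefm. They were -1.62 for Hsd3b1, -1.53 for Ddx6, -1.35 for Cyp11b1, -1.32 for Gm42035, -1.31 for Myh3, -1.27 for Col10a1, -1.25 for Ttn and -1.19 for Smco3. Without the dye term none of the 15 passed. The comparison uses the labelled sex, and with the arrays of replicates 1 and 4, whose sex chromosome transcripts were at intermediate levels in both RNAs, left out, 1 array of each sex remains and the difference has no test.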

How the results depend on the processing

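The fit to replicates 2 and 3 alone and the sex test without a dye term were chosen after the data were examined. All 266 genes changed kept their direction in every alternative that measured them. For the 263 with the same sign on all 4 arrays, leaving out an array, array weights or another variance model could not have reversed it. Of 57 named genes besides Trp63, none reversed and 29 stayed past the threshold in every alternative in which they were followed. They were not followed with a 1.5-fold minimum or with every probe tested by itself. Without a filter on dim probes 27 of the 57 missed the threshold. Trp63 passed in each alternative, at -0.87 for the mean of its kept probes and -1.48 to -1.26 with 1 array left out. The count of 266 (153 lower, 113 higher) became 430 (245, 185) with scaling between arrays, 460 (266, 194) without the dye term, 543 (310, 233) with a sex term, 86 (55, 31) without the filter on dim probes, and 1564 (683, 881) on replicates 2 and 3 alone, also without the dye term. Leaving out 1 array gave 283 to 1608 genes changed, 155 to 855 lower and 128 to 753 higher (171 higher without replicate 1), with 1 residual degree of freedom. With no replicate block, taking the 8 channels as separate RNAs, 387 genes changed. The count of 13 shifted lists became 0 with an estimated correlation (camera, 2 at an unadjusted p under 0.05), 6 on replicates 2 and 3 alone, and 9 to 14 with 1 array left out. The 15 genes called for a sex difference became 34 with Agilent's processed signals, 0 without the filter, 7 with a trended and robust variance and 0 without the dye term. The dye effect rose from 0 to 656 genes with median centring in place of loess. The cause was not tested. All 20 alternatives fixed at the start were run. Signal over background limits the calls to the 28611 probes kept.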

Other observations

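The marker lists used in this part were written after the data had been examined, and their results are given as values.

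Genes of ureteral pacemaker and interstitial cells, which set the rhythm of peristalsis, did not pass the test. Of 7 such genes, 6 were tested and none changed, with a median log2 ratio of 0.01. Kit was at -0.15 ± 0.03 and Ano1 at 0.29 ± 0.40 (SD, n = 4).

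Of 18 genes of epidermis and limb epithelium, 14 were tested, and 6 were lower: Serpinb5, Trim29, Lypd3, Wnt10a, Wnt6 (-1.64 ± 0.17) and Fat2 (-1.20 ± 0.19). The other tested members did not pass, with Sp6 at -0.35 ± 0.16, Krt1 at -0.19 ± 0.42, Lef1 at -0.12 ± 0.16, Dlx3 at -0.09 ± 0.10, Sp8 at -0.04 ± 0.11, Krt10 at -0.04 ± 0.13, Wnt10b at 0.06 ± 0.09 and Msx2 at 0.29 ± 0.23. This list holds genes picked after their decrease had been seen, so its count is not independent evidence.

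Of 18 tested fetal liver genes, Ttr rose and 0 fell (limma). Ahsg at -0.89 ± 0.45, Serpina1a at -0.78 ± 0.52 and Apoh at -0.62 ± 0.30 were below 0 on all 4 arrays without passing the test, while Rbp4 at 0.21 ± 0.16 was above 0 on all 4 without passing. Clec16a, a neighbour of Prm1 on chromosome 16, was lower at -0.47 ± 0.17 (adjusted p = 0.0467).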
